A study of Rattus norvegicus with 18 samples.

How the data were processed

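Messenger RNA of rat dorsal root ganglia was measured by sequencing in 18 libraries, 3 in each of 6 groups named in the labels Ctrl, Ctrl_solvent, Sham_solvent, Sham_herb, NPP_solvent and NPP_herb. Per the labels' protocols, total RNA was extracted with TRIZOL and treated with DNase, messenger RNA was captured on beads, libraries were made with a KAPA stranded kit, and fragments were read from both ends on an Illumina NovaSeq instrument. HISAT2, DESeq2 and the genome build mRatBN7.2 are named in the submitters' processing notes, without versions. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart with certainty. Such genes here include the hemoglobin genes, the complement pair C4a and C4b, the MHC class II genes and the ribosomal RNA genes Rn45s and Rn28s.

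The deposited count table holds raw reads per gene, whole numbers that the authors did not normalize, for 25678 genes. A deposited FPKM table gives reads scaled to gene length and to library size (FPKM), scaled by the authors and rounded, for 25557 of the same genes (121 are missing from it). Each library has its own column in both tables and no replicates were pooled. Gene identifiers in the tables are the prefix gene- followed by a symbol, and 146 symbols were repeated. Where a symbol was repeated, the identifier equal to the plain symbol was used. Chromosomes are those the tables give on mRatBN7.2. The tables give no start or end, and the gene table at hand was built on another assembly, so no coordinates from it were used. Gene lengths implied by the counts and FPKM differed between libraries by a median coefficient of variation of 0.349% over 5534 genes, so both tables were taken to rest on the same reads.

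Genes with too few reads were removed with the filterByExpr function of edgeR, which left 17043 genes for testing. The 8635 genes removed held at most 0.0495% of the reads of any library. Libraries were scaled by TMM factors, which ran from 0.946 to 1.04. The test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with robust dispersion, on all 18 libraries in one model with 1 coefficient per group, which left 12 residual degrees of freedom. Adjusted p is the Benjamini-Hochberg value over all genes tested in a comparison, with a threshold of 0.05. Replicates within a group correlated across genes at a median r of 0.977 on log2 CPM, and no pair agreed within sampling noise (the smallest chi-square per degree of freedom was 12.1), so none was counted as a repeat. CPM values are counts scaled to the size of the library after TMM, given as mean ± SD over the 3 libraries of a group.

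Comparisons were NPP_solvent with Sham_solvent, NPP_herb with NPP_solvent, Sham_herb with Sham_solvent, NPP_herb with Sham_herb, Sham_solvent with Ctrl_solvent, Ctrl_solvent with Ctrl, NPP_solvent with Ctrl_solvent, and the difference of the herb effect between the NPP and Sham arms. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Alternatives added afterwards are said to be so.

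The 29 gene lists covered the nerve injury response, nociceptor genes, potassium channels of sensory neurons, large-diameter neuron genes, pan-neuronal genes, satellite glia, myelinating Schwann cells, cholesterol synthesis, macrophages, T and B cells, neutrophils, red blood cells, fibroblasts and matrix, endothelial and mural cells, spinal cord, skeletal muscle, adipocytes, inflammatory mediators, interferon-stimulated genes, MHC class II, complement, immediate early genes, the circadian clock, glucocorticoid-responsive genes, heat shock, hypoxia, NRF2 and AhR targets, the cell cycle and inflammation-linked transcription factors. Some genes sit in several lists, such as C1qa, C1qb and C1qc in the macrophage and complement lists. Between 6 genes (adipocyte) and 43 genes (transcription factors) of a list were tested. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, 2-sided, against all other tested genes, with adjustment over the lists of a comparison. Camera with a correlation estimated from the data and the rotation test fry were run beside it. A list's change is its mean log2 fold change with the SE over members, and a list's score in a library is the mean over members of log2 CPM minus the gene's mean over the 18 libraries.

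Named genes followed a rule. For the comparisons of NPP_solvent with Sham_solvent, NPP_herb with NPP_solvent and Sham_herb with Sham_solvent, up to 10 genes per direction were to be named by largest change among those with adjusted p under 0.05, a mean of at least 1 CPM, groups that did not overlap and a symbol that is not a placeholder, and up to 5 in the others. Where fewer than 5 genes passed in a direction, the list was filled to 5 with the smallest unadjusted p among genes meeting the other criteria. For each list that passed, up to 4 members with the smallest adjusted p were added. The injury genes Atf3, Sox11, Gal, Npy, Vip, Sprr1a, Csf1 and Gadd45a, the inflammatory genes Il1b, Il6, Tnf, Ccl2, Cxcl10 and Cd68, the transcription factors Jun, Fos, Stat3, Irf7, Irf8, Spi1 and Cebpb, and the sex-linked genes Xist, Ddx3y, Kdm5d and Eif2s3y were fixed in every case. Il6 had 61 reads in all and was below the filter, and Xist is not listed in the table used.

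Alternatives were DESeq2 size factors in edgeR, no filter, a stricter filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, only the compared groups in the model, the replicate number as a block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, and leaving out each library in turn. Added after the data were seen were leaving out every library numbered 3, leaving out Ctrl_solvent replicates 1 and 3, leaving out Ctrl replicates 2 and 3, and using as a covariate each library's slope of log2 CPM on log2 gene length. Lengths came from the counts and FPKM for 14073 genes, with a median of 3569 bases.

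The tests were checked on simulated counts of 17043 genes, in 3 runs with 200 genes changed in NPP_solvent each, for NPP_solvent against Sham_solvent. Gene means were those over all 18 libraries, dispersions came from the model of all 6 groups, and library sizes were the real ones. EdgeR called 59.3% of the genes changed 2-fold and 79.3% of those changed 4-fold, with a false share of 3.93%. For DESeq2 these values were 68.3%, 84.3% and 15.8%, and for voom 59.7%, 78.0% and 4.18%. Camera called a shifted list of 25 genes in 3 of 3 runs and 0 of 75 random lists. Simulated genes were independent of each other, so these runs say nothing on the preset correlation in lists of correlated genes. Counts of genes and lists called were also taken for splits of the same samples, 100 in all with the real split of each comparison.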

Results

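Gene expression was measured by messenger RNA sequencing in dorsal root ganglia of rats, the ganglia that hold the cell bodies of sensory neurons together with glia, vessels and resident immune cells. The study's design text describes a rat model of neuropathic pain and Shentong Zhuyu decoction, a traditional preparation of 12 ingredients, and asks through which genes and transcription factors the decoction acts. The 18 libraries fell into 6 groups of 3, named Ctrl, Ctrl_solvent, Sham_solvent, Sham_herb, NPP_solvent and NPP_herb after the state of the animals (Ctrl, Sham or NPP) and their treatment (solvent or herb). How the model was made, the dose and the time of sampling are not given in the sources used here. The sources do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. In Ctrl replicates 1, 2 and 3 the Y-linked Eif2s3y had 3006, 1 and 0 reads and Kdm5d 334, 0 and 0. These values argue against 1 animal behind all of that group. Depth, in 1e6 counted reads, ran from 18.2 (Ctrl_solvent replicate 1) to 50.3 (Sham_solvent replicate 2) with a median of 28.4. In each library 19579 to 21442 genes had at least 1 read. Levels are given as CPM (counts scaled to library size), mean ± SD with n = 3 per group, and changes as log2 fold change ± SE.

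The mitochondrially encoded genes took 7.72% to 11.4% of reads, ribosomal protein genes 1.52% to 3.37%, and the 10 most abundant genes 9.32% to 12.4%. Hemoglobin genes took 0.000455% of reads in Ctrl_solvent replicate 3 and up to 0.0815% in Sham_solvent replicate 3. Ribosomal RNA took 0.219% to 0.599%, with a mean of 0.466 ± 0.148% in NPP_herb and 0.263 ± 0.0187% in NPP_solvent. Log2 CPM correlated across genes at a median r of 0.977 within groups (0.961 to 0.985) and 0.975 between groups (0.951 to 0.988), so libraries of one group were hardly more alike than libraries of different groups. The first and second principal components held 21.1% and 15.04% of the variance.

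No gene passed the edgeR test in any of the 8 comparisons, and the genes named below are those with the smallest unadjusted p, members of gene lists that passed, and genes fixed in advance. Of 232 tests of 29 gene lists with camera, 76 passed with the preset correlation between genes, 9 passed with fry, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.0916. The estimated correlation had a median of 0.315 and reached 0.857, so adjusted p with the preset 0.01 rest on a value far below that median. For the 76 lists that passed, mean, median and direction of the test had one sign, and these differed in sign in 29 of the 156 that did not pass. Because no gene passed over all genes tested, the number of members that did was 0 for every list, and only counts adjusted over the list alone are given below.

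The comparison of NPP_solvent with Sham_solvent asks what the pain model changed in the ganglia of animals given solvent. Genes of nociceptors, the neurons that sense harmful stimuli, rose as a group by a mean log2 fold change of 0.36 ± 0.08 (SE over members), with 24 of 27 members higher (camera, adjusted p = 4.09e-06, but adjusted p = 0.988 with an estimated correlation). Among them the heat and capsaicin channel Trpv1 was at 92.3 ± 5.73 CPM against 64.8 ± 9.89, the irritant channel Trpa1 at 39.8 ± 16.7 against 19.97 ± 8.66, and the ATP-gated channel P2rx3 at 447 ± 24.8 against 361 ± 27.1. The mean nociceptor score was 0.13 in NPP_solvent and -0.23 in Sham_solvent, but 0.15 in Ctrl. The rise is therefore one over Sham_solvent, and NPP_solvent did not lie above Ctrl. Nerve injury response genes, which sensory neurons switch on after axon damage, rose by 0.70 ± 0.21, with 22 of 24 higher (camera, adjusted p = 0.00322, and adjusted p = 0.988 with an estimated correlation). In that list the gabapentin-binding calcium channel subunit Cacna2d1 was at 10.6 ± 5.77 CPM against 3.53 ± 1.83, the endopeptidase Ecel1 at 6.14 ± 4.63 against 2.21 ± 0.689 and the neuropeptide gene Adcyap1 at 112 ± 16.5 against 74.0 ± 16.5. Reg3b, a secreted lectin, was at 16.1 ± 17.9 CPM against 0.878 ± 0.589, but its mean rests on NPP_solvent replicate 3 (36.6 CPM), which had the lowest Atf3 of its group (14.0), and it was at 67.1 and 97.1 in Ctrl replicates 2 and 3. Neutrophil genes fell by 0.84 on the log2 scale in 12 of 12 members (camera, adjusted p = 0.00388, and adjusted p = 0.988 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, was at 15.7 ± 1.16 CPM against 42.1 ± 14.1, and Cd177 at 0.409 ± 0.309 against 1.55 ± 0.882. Red blood cell genes lay the same way and did not pass (-0.85, camera adjusted p = 0.142), and hemoglobin genes took 0.00755 ± 0.00702% of reads against 0.0318 ± 0.0433%. Heat shock genes fell by 0.19 in 12 of 15 members (camera, adjusted p = 0.0211, and adjusted p = 0.988 with an estimated correlation). The inducible chaperone Hspa1b was at 16.1 ± 7.26 CPM against 38.7 ± 29.5. Adjusted over the list alone, 0 members of these 4 lists passed.

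Classical injury markers spread widely within the groups. The transcription factor Atf3 (chromosome 13), a standard marker of injured sensory neurons, was at 45.5 ± 34.9 CPM in NPP_solvent and 18.9 ± 9.14 in Sham_solvent (log2 fold change 1.26 ± 1.01, edgeR adjusted p = 0.781). The neuropeptide genes Npy (60.6 ± 58.7 against 11.6 ± 15.3 CPM) and Gal (28.6 ± 20.4 against 15.8 ± 7.39 CPM) spread as much, and Sox11, Vip, Sprr1a, Csf1 and Gadd45a had log2 fold changes of 0.56, 1.39, 2.43, 0.18 and 0.20. Atf3 in single libraries was 83.1, 39.4 and 14.0 CPM in NPP_solvent, 50.9, 107 and 10.8 in NPP_herb, 12.96, 14.4 and 29.4 in Sham_solvent, 11.6, 10.7 and 54.5 in Sham_herb, 15.9, 10.4 and 94.6 in Ctrl_solvent, and 9.69, 9.60 and 9.53 in Ctrl. The inflammatory genes Il1b (1.15 ± 0.14 against 0.883 ± 0.61 CPM), Tnf (0.167 ± 0.0798 against 0.0837 ± 0.0807), Ccl2 (16.9 ± 5.65 against 15.6 ± 6.57), Cxcl10 (11.3 ± 6.91 against 13.5 ± 8.32) and Cd68 (8.60 ± 4.02 against 5.79 ± 3.36) did not pass edgeR's test either. The transcription factor Stat3 was at 224 ± 8.19 CPM against 183 ± 23.1, with an unadjusted p of 0.0128, and Jun, Fos, Irf7, Irf8, Spi1 and Cebpb had log2 fold changes of 0.35, -0.11, 0.93, 0.00, 0.09 and -0.59.

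The genes with the smallest unadjusted p for NPP_solvent against Sham_solvent were, upward, Tmem158 (chromosome 8, 10.2 ± 3.72 against 3.89 ± 0.757 CPM), the receptor phosphatase Ptprt (chromosome 3, 37.6 ± 9.55 against 20.9 ± 1.92 CPM), Bves, Slc29a4 and Prelid2. Downward they were the gap junction gene Gjb2 (chromosome 15, 1.85 ± 0.532 against 4.16 ± 0.967 CPM), the hyaluronan-degrading Cemip (chromosome 1, 4.45 ± 0.484 against 7.98 ± 2.17 CPM), Sh3bgr, Ucma and Sptssb. EdgeR called 0 of 17043 genes, the smallest adjusted p was 0.755, and 967 genes had an unadjusted p under 0.05 (453 higher, 514 lower). The last count was 374, 3432 and 577 without Sham_solvent replicates 1, 2 and 3, 1605 and 428 without NPP_solvent replicates 2 and 3, and 516 with the gene length covariate. DESeq2, voom and both fits of the FPKM table also called 0. In 1383 genes (8.11%) the groups did not overlap, where chance gives 10%. Leaving out NPP_solvent replicate 1 or Sham_solvent replicate 2 ended the nerve injury call (mean 0.46 and 0.50, camera adjusted p = 0.143 and 0.280). Leaving out Sham_solvent replicate 2 or 3 ended the neutrophil call (-0.91 and -0.57), and leaving out NPP_solvent replicate 2 or Sham_solvent replicate 2 or 3 ended that of heat shock (-0.20, -0.23 and -0.08). With each library's gene length slope as a covariate, an alternative chosen after seeing the data, the nociceptor mean was 0.21 and still passed, and large-diameter neuron (-0.14), cholesterol synthesis (0.08), interferon-stimulated (0.59) and transcription factor (0.18) lists passed too.

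**Figure D1:**
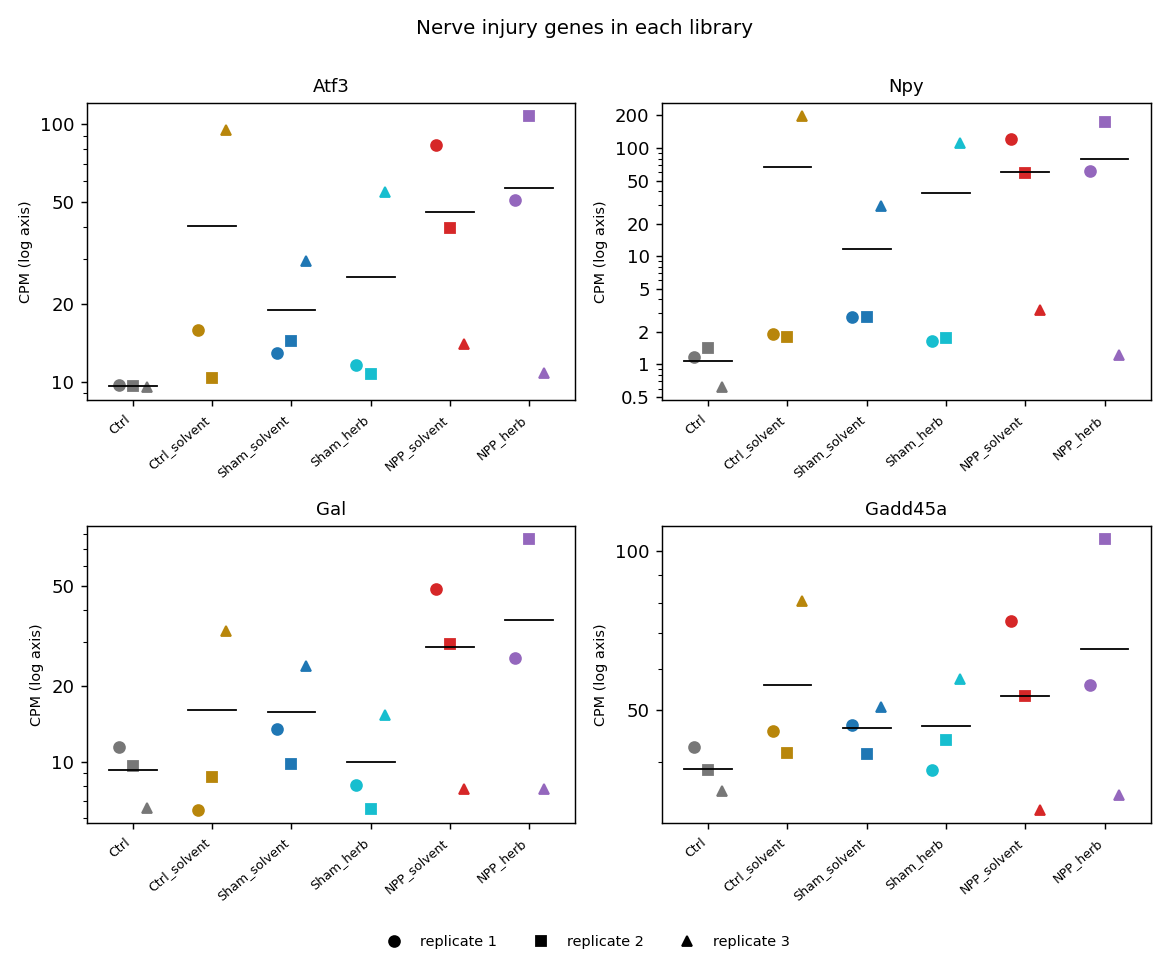
CPM (log axis) of the injury genes Atf3, Npy, Gal and Gadd45a in each of the 18 libraries by group, with symbols for replicates 1 (circle), 2 (square) and 3 (triangle) and bars at the group mean. Atf3 was 39.4 to 107 CPM in replicates 1 and 2 of both NPP groups, high also in replicate 3 of Ctrl_solvent (94.6), Sham_herb (54.5) and Sham_solvent (29.4), and it was 14.0 and 10.8 in replicate 3 of NPP_solvent and NPP_herb.

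The comparison of NPP_herb with NPP_solvent asks what the herb treatment changed in the pain model. Interferon-stimulated genes, the antiviral program downstream of interferon receptors, fell by 1.37 on the log2 scale in 28 of 28 members (camera, adjusted p = 1.89e-13, but adjusted p = 0.618 with an estimated correlation). Isg15, a ubiquitin-like protein, was at 4.93 ± 0.806 CPM in NPP_herb against 77.7 ± 66.0 in NPP_solvent, and the interferon transcription factor Irf7 at 11.02 ± 1.16 against 98.2 ± 79.9. The spread lay in NPP_solvent, where Isg15 was 108, 123 and 2.01 CPM in replicates 1, 2 and 3. Complement genes fell by 0.52 in 17 of 20 members (camera, adjusted p = 0.00432, and adjusted p = 0.897 with an estimated correlation). C1qa, a subunit of the complement starter C1q that macrophages make, was at 18.9 ± 2.71 CPM against 50.1 ± 29.3, and C4a at 20.7 ± 6.84 against 89.2 ± 69.9. Macrophage genes, a list that shares C1qa, C1qb and C1qc with the complement list, lay the same way and did not pass (-0.32, camera adjusted p = 0.145).

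Red blood cell genes rose by 1.53 ± 0.29 in NPP_herb, with 11 of 13 higher, and neutrophil genes by 0.76 ± 0.13, with 12 of 12 higher (camera, adjusted p = 8.76e-05 and 0.000288, both with adjusted p = 0.618 with an estimated correlation). The red cell anion exchanger Slc4a1 was at 2.73 ± 3.59 CPM against 0.373 ± 0.0991, and Cd177 at 1.33 ± 1.27 against 0.409 ± 0.309. Hemoglobin genes took 0.0134%, 0.0186% and 0.0750% of reads in NPP_herb replicates 1, 2 and 3. In NPP_solvent they took 0.00210%, 0.00507% and 0.0155%. Blood left in the ganglia was not tested as a source of the red blood cell and neutrophil calls. Endothelial and mural genes rose by 0.16 ± 0.04 in 16 of 19 members and cholesterol synthesis genes by 0.06 ± 0.02 in 16 of 22 (camera, adjusted p = 0.00013 and 0.0425, both with adjusted p = 0.618 with an estimated correlation). The receptor Notch3, which mural cells carry, was at 22.0 ± 2.50 CPM against 17.8 ± 0.944, the contractile gene Tagln at 35.4 ± 5.72 against 21.7 ± 2.14, and Insig1, a sterol-regulated inhibitor of cholesterol synthesis, at 194 ± 10.7 against 175 ± 10.3. Of the members of these 6 lists, 0 passed adjusted over the list alone.

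Injury genes did not differ beyond their spread between NPP_herb and NPP_solvent. Atf3 was at 56.3 ± 48.5 against 45.5 ± 34.9 CPM, Npy at 78.6 ± 86.9 against 60.6 ± 58.7 and Gal at 36.7 ± 35.7 against 28.6 ± 20.4. The log2 fold changes of Sox11, Vip, Sprr1a, Csf1 and Gadd45a were 0.34, 0.82, 0.67, 0.19 and 0.29. The inflammatory genes had log2 fold changes of 1.35 ± 0.75 (Il1b), -1.10 ± 1.13 (Tnf), 0.11 ± 0.52 (Ccl2), -1.55 ± 1.06 (Cxcl10) and -1.08 ± 0.53 (Cd68), each with an edgeR adjusted p of 1. Among the fixed transcription factors, Fos was at 7.76 ± 5.35 CPM against 3.07 ± 1.21 and Stat3 at 209 ± 15.7 against 224 ± 8.19, while Jun, Irf8, Spi1 and Cebpb had log2 fold changes of 0.01, -0.18, -0.30 and -0.09.

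Several of the genes with the smallest unadjusted p were those of the model comparison with the opposite sign. Gjb2 was at 4.07 ± 0.366 CPM in NPP_herb against 1.85 ± 0.532 in NPP_solvent, Cemip at 7.82 ± 0.85 against 4.45 ± 0.484, and Tmem158 at 3.64 ± 1.57 against 10.2 ± 3.72. Both comparisons share the NPP_solvent libraries, so chance values in those libraries enter both with opposite sign. The neuronal exchange factor Rasgrf1 (chromosome 8, 11.5 ± 1.42 against 7.36 ± 0.844 CPM), the ribosomal RNA precursor Rn45s (2676 ± 1338 against 968 ± 115 CPM) and Pimreg completed the upward genes. The others downward were Abcg3l4, Trim11, Wnt11 and the calcium sensor Scgn (chromosome 17, 1.79 ± 0.164 against 4.08 ± 0.309 CPM). EdgeR called 0 of 17043 genes, the smallest adjusted p was 1, and 319 genes had an unadjusted p under 0.05 (155 higher, 164 lower), or 501 without NPP_herb replicate 3 and 577 without NPP_solvent replicate 3. DESeq2, voom and the FPKM fits called 0 too. Groups did not overlap in 903 genes (5.30%, chance 10%). With the preset correlation the interferon call held with each library left out, at -2.20 without NPP_solvent replicate 3. That list did not pass with an estimated correlation (camera, adjusted p = 0.618) or with fry, and these were not run with libraries left out. Leaving out NPP_herb replicate 3 ended the neutrophil (0.38), red blood cell (0.93) and complement (-0.43) calls, NPP_herb replicate 1 the endothelial call (0.05), NPP_solvent replicate 2 the complement call (-0.40), and NPP_herb replicate 2 or NPP_solvent replicate 1 or 2 the cholesterol call (0.03, 0.05 and 0.04). Complement genes were at -0.78 without NPP_solvent replicate 3.

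The comparison of Sham_herb with Sham_solvent asks what the herb treatment did without the model. Glucocorticoid-responsive genes fell by 0.42 on the log2 scale in 12 of 14 members (camera, adjusted p = 0.000666, but adjusted p = 0.88 with an estimated correlation), and 3 members passed adjusted over the list alone. The glucocorticoid-induced leucine zipper Tsc22d3 was at 220 ± 12.7 CPM against 311 ± 27.6, the kinase Map3k6 at 2.41 ± 0.213 against 4.47 ± 0.551 and the receptor feedback inhibitor Errfi1 at 19.5 ± 2.72 against 28.0 ± 4.04. Heat shock genes fell by 0.23 in 13 of 15 members (camera, adjusted p = 0.00466, and adjusted p = 0.88 with an estimated correlation), 3 of them adjusted over the list alone. The co-chaperone Dnajb1 was at 58.6 ± 2.71 CPM against 83.7 ± 18.9 and Hspa1b at 14.4 ± 1.81 against 38.7 ± 29.5. Fibroblast and matrix genes fell by 0.39 in 17 of 20 members (camera, adjusted p = 0.00262, and adjusted p = 0.88 with an estimated correlation), 1 of them adjusted over the list alone. The matrix protein Fbln1 was at 8.67 ± 1.11 CPM against 15.2 ± 0.42 and the proteoglycan Dcn at 466 ± 101 against 674 ± 75.0.

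Macrophage genes fell by 0.45 in 20 of 22 members, neutrophil genes by 0.72 in 12 of 12 and red blood cell genes by 1.02 in 13 of 13 (camera, adjusted p = 0.00641, 0.0182 and 0.0225, all with adjusted p = 0.88 with an estimated correlation, 0 members adjusted over the list alone). Other immune lists did not pass, with means of 0.07 for T and B cell genes, 0.10 for inflammatory mediators, -0.10 for interferon-stimulated genes and -0.46 for MHC class II genes. The vessel-associated macrophage receptor Lyve1 was at 3.56 ± 1.20 CPM against 6.69 ± 2.91, while the fractalkine receptor Cx3cr1 lay the other way, at 1.11 ± 0.252 against 0.369 ± 0.126. The hemoglobin gene Hba-a1 was at 19.7 ± 4.86 CPM against 124 ± 165. Immediate early genes, which cells switch on within minutes of a stimulus, fell by 0.36 in 21 of 24 members (camera, adjusted p = 0.00206, and adjusted p = 0.88 with an estimated correlation, 0 adjusted over the list alone). The flow-responsive factor Klf2 was at 1.37 ± 0.219 CPM against 3.09 ± 1.37 and Jund at 76.0 ± 8.14 against 108 ± 37.9.

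Nociceptor genes rose in Sham_herb by 0.25 ± 0.09 in 19 of 27 members (camera, adjusted p = 0.00206, and adjusted p = 0.88 with an estimated correlation), 1 of them adjusted over the list alone, the nociceptor lineage factor Runx1, at 36.8 ± 1.64 CPM against 27.4 ± 0.707. The nociceptor rises in Sham_herb and in NPP_solvent share the Sham_solvent libraries, whose mean nociceptor score (-0.23) was the lowest of the 6 groups. Large-diameter neuron genes (-0.02) and pan-neuronal genes (0.03) did not pass. The factor Prdm12, which nociceptors need to form, was at 34.0 ± 2.49 CPM against 22.3 ± 9.06, and the itch and touch receptor Mrgprd at 6.26 ± 0.415 against 2.31 ± 2.38. Potassium channel genes rose by 0.21 ± 0.07 in 20 of 28 members (camera, adjusted p = 0.0452, and adjusted p = 0.959 with an estimated correlation). Kcnd3 was at 102 ± 11.5 CPM against 77.2 ± 6.11. Cholesterol synthesis genes rose by 0.17 ± 0.07 in 17 of 22 members (camera, adjusted p = 0.00467, and adjusted p = 0.88 with an estimated correlation). The late enzyme of that pathway Sc5d was at 184 ± 5.87 CPM against 146 ± 14.5. Adjusted over the list alone, 0 potassium channel and 0 cholesterol genes passed.

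Of the fixed genes, the transcription factor Cebpb was at 3.12 ± 0.658 CPM in Sham_herb against 7.13 ± 2.33 in Sham_solvent (unadjusted p = 0.00205) and Stat3 at 215 ± 5.87 against 183 ± 23.1, while Atf3 was at 25.6 ± 25.04 against 18.9 ± 9.14. Il1b, Tnf, Ccl2, Cxcl10 and Cd68 had log2 fold changes of 0.32, 1.20, 0.00, -0.54 and -0.71, and none passed edgeR's test. The genes with the smallest unadjusted p were, upward, Prelid2 (60.0 ± 2.70 against 46.3 ± 2.40 CPM), Ldb2, the zinc and manganese carrier Slc39a8, Fam149a (chromosome 16, 20.01 ± 0.908 against 12.3 ± 0.454 CPM) and the calcium-activated potassium channel Kcnn1 (chromosome 16, 11.1 ± 1.65 against 6.71 ± 0.304 CPM). Downward they were Fbln1 (chromosome 7), Ndufaf2, Scand1, Dnajb1 and the growth factor Bmp7 (1.02 ± 0.269 against 2.91 ± 1.28 CPM). EdgeR called 0 of 17043 genes with a smallest adjusted p of 0.491, and 1686 genes had an unadjusted p under 0.05 (750 higher, 936 lower). The last count was 501, 4235 and 1040 without Sham_solvent replicates 1, 2 and 3, 890 and 1090 without Sham_herb replicates 2 and 3, and 447 with the gene length covariate. DESeq2 and the FPKM fits called 0, whereas voom with sample quality weights called 1131. Groups did not overlap in 2485 genes (14.6%, chance 10%).

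Leaving out single libraries ended most list calls of Sham_herb against Sham_solvent. These were the macrophage call without Sham_herb replicate 1 (-0.21) or Sham_solvent replicate 2 (-0.25), the neutrophil call without these (-0.45 and -0.79) or Sham_solvent replicate 3 (-0.46), and the red blood cell call without Sham_herb replicate 1 (-0.85) or Sham_solvent replicate 3 (-0.20). Also ended were the fibroblast call without Sham_herb replicate 1 (-0.26), the glucocorticoid call without Sham_solvent replicate 2 (-0.27), the heat shock call without Sham_solvent replicate 3 (-0.11), the cholesterol call without Sham_solvent replicate 2 (0.16) and the potassium channel call without Sham_herb replicate 1 (0.20) or Sham_solvent replicate 1 (0.10) or 3 (0.19). Macrophage genes were at -0.72 without Sham_herb replicate 2, red blood cell genes at -1.69 and potassium channels at 0.32 without Sham_solvent replicate 2, and glucocorticoid-responsive genes at -0.24 without Sham_herb replicate 1. The nociceptor and immediate early calls held with each library left out but ended with the gene length slope as a covariate (0.04 and -0.11), as did potassium channels (-0.02), while large-diameter neuron (-0.11), nerve injury (0.49) and circadian clock (-0.22) lists passed with it.

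The comparison of NPP_herb with Sham_herb asks what the model changed in animals given the herb. Nerve injury genes rose by 0.77 ± 0.14 in 24 of 24 members (camera, adjusted p = 1.44e-07, but adjusted p = 0.683 with an estimated correlation). Ecel1 was at 6.66 ± 3.80 CPM against 2.28 ± 0.372 and Gal at 36.7 ± 35.7 against 9.94 ± 4.68. Immediate early genes rose by 0.45 ± 0.12 in 22 of 24 members (camera, adjusted p = 1.44e-07, and adjusted p = 0.683 with an estimated correlation). The activity-dependent factors Fosb was at 4.98 ± 5.64 CPM against 0.465 ± 0.199 and Fos at 7.76 ± 5.35 against 2.37 ± 0.342. Red blood cell genes (1.71 ± 0.30, 13 of 13), fibroblast genes (0.32 ± 0.05, 19 of 20), cell cycle genes (0.31 ± 0.08, 20 of 24) and endothelial genes (0.11 ± 0.04, 14 of 19) rose too (camera, adjusted p = 2.61e-07, 2.81e-05, 1.66e-05 and 0.026, all with adjusted p = 0.683 with an estimated correlation). Neutrophil genes (0.64 ± 0.09, 12 of 12) and skeletal muscle genes (0.37 ± 0.13, 13 of 16) rose and interferon-stimulated genes fell by 0.85 in 28 of 28 members (camera, adjusted p = 0.00185, 0.0439 and 2.94e-06, with adjusted p = 0.778, 0.846 and 0.846 with an estimated correlation). The guanylate-binding gene Gbp2 was at 26.3 ± 9.02 CPM against 64.9 ± 48.4, the mitotic gene Birc5 at 3.46 ± 1.14 against 1.91 ± 0.678 and the muscle myosin Myh1 at 1.05 ± 1.07 against 0.294 ± 0.114. In these 9 lists 0 members passed adjusted over the list alone.

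Among genes with the smallest unadjusted p, the protease inhibitor A2m (chromosome 4) was at 54.9 ± 2.17 CPM in NPP_herb against 34.2 ± 3.05 in Sham_herb and Klf2 at 2.94 ± 0.233 against 1.37 ± 0.219. The precursor Rn45s was at 2676 ± 1338 against 794 ± 91.6, beside Rn28s and Misp. Tram1l1 was at 16.4 ± 1.49 CPM against 22.0 ± 0.701, beside Med17, Wdr45, Pik3c3 and Naaladl2. Atf3 was at 56.3 ± 48.5 CPM against 25.6 ± 25.04. EdgeR called 0 genes (smallest adjusted p 0.228) and 238 had an unadjusted p under 0.05 (138 higher, 100 lower), or 447 without NPP_herb replicate 3 and 429 with the gene length covariate. DESeq2 called 2, LOC120102105 and Rn45s, and voom and the FPKM fits called 0. Groups did not overlap in 1252 genes (7.35%, chance 10%). Leaving out NPP_herb replicate 2 ended the nerve injury call (0.33, camera adjusted p = 0.172), which was 1.30 without NPP_herb replicate 3. Leaving out NPP_herb replicate 3 ended the neutrophil and muscle calls (0.27 and 0.01), and Sham_herb replicate 1 those of neutrophil, fibroblast, endothelial and muscle genes (0.37, 0.18, 0.08 and 0.30). Leaving out Sham_herb replicate 3 ended those of endothelial and muscle genes (0.09 and 0.37), and NPP_herb replicate 1 those of fibroblast and endothelial genes (0.16 and -0.0028). Immediate early genes were at 0.26 without NPP_herb replicate 2 and 0.68 without replicate 3, and red blood cell genes at 1.11 without NPP_herb replicate 3. Interferon-stimulated genes were at -0.51 without Sham_herb replicate 1 and -1.32 without replicate 3, and fibroblast and endothelial genes at 0.48 and 0.19 without Sham_herb replicate 2. Muscle genes were at 0.64 without NPP_herb replicate 1, and with the gene length covariate the muscle (0.35) and endothelial (0.10) calls ended, as did the muscle call with DESeq2 size factors (0.38).

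The plot of list scores shows the nociceptor, interferon, macrophage and red blood cell lists side by side in all groups.

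**Figure D2:**
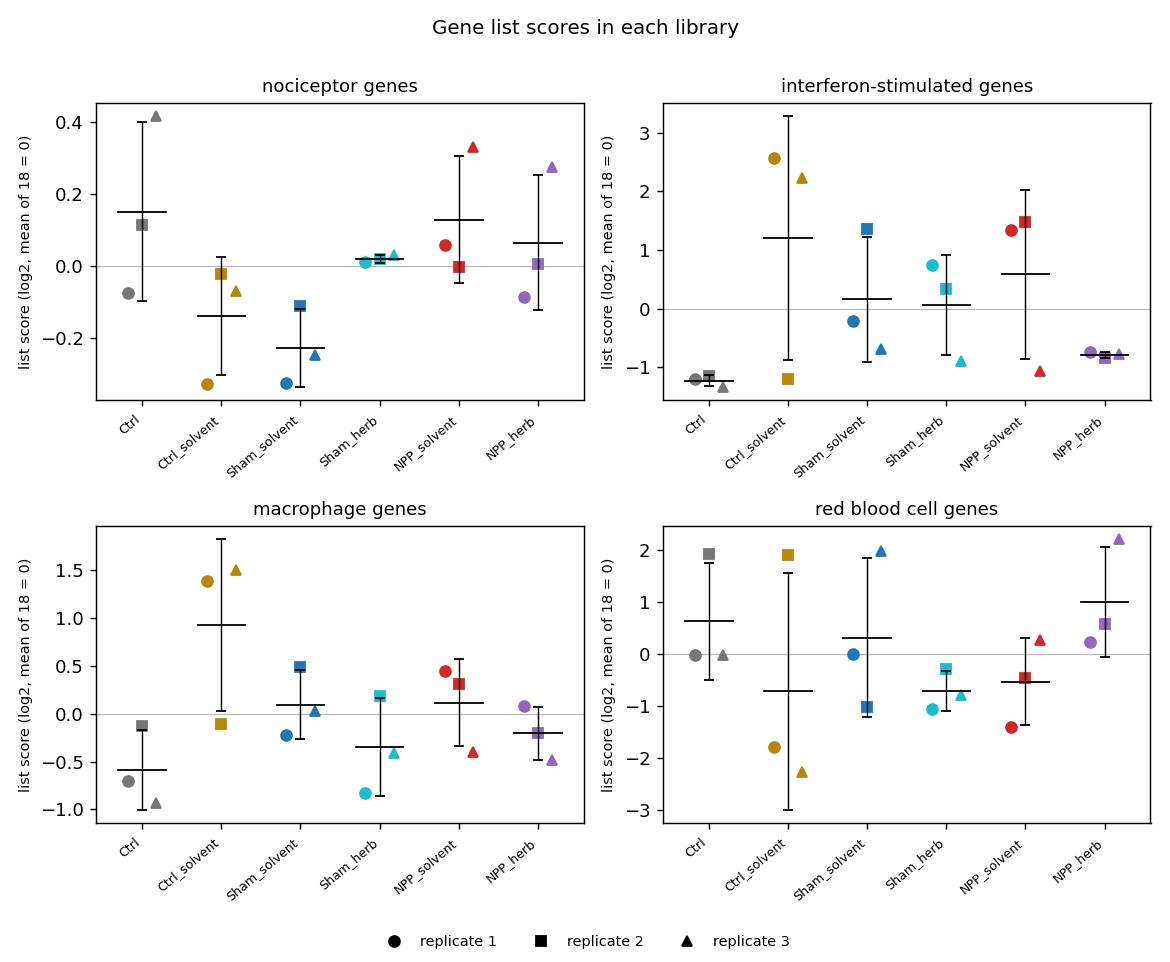
Scores of the nociceptor, interferon-stimulated, macrophage and red blood cell lists in each library (mean over members of log2 CPM minus the mean of the 18 libraries, so that 0 is the average library), with bars for group mean ± SD. The interferon score spread with an SD of 2.08 in Ctrl_solvent and 1.43 in NPP_solvent against 0.0947 in Ctrl and 0.0553 in NPP_herb. The mean nociceptor score was 0.15 in Ctrl, -0.14 in Ctrl_solvent, -0.23 in Sham_solvent, 0.02 in Sham_herb, 0.13 in NPP_solvent and 0.07 in NPP_herb.

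The comparison of Sham_solvent with Ctrl_solvent asks what the sham procedure changed. Inflammatory mediators fell by 1.37 in 31 of 32 members, T and B cell genes by 1.70 in 13 of 14, and cell cycle genes by 0.99 in 24 of 24 (camera, adjusted p = 2.58e-16, 2.64e-11 and 1.29e-19, with adjusted p = 0.189, 0.102 and 0.102 with an estimated correlation). In that order 20, 11 and 17 members passed adjusted over the list alone. The chemokine Ccl5 was at 0.949 ± 0.332 CPM against 9.24 ± 7.22, the killer T cell receptor Cd8a at 0.288 ± 0.102 against 5.29 ± 4.001 and the replication gene Mcm5 (chromosome 19) at 1.81 ± 0.191 against 5.89 ± 2.21. MHC class II genes fell by 1.33 in 10 of 10, complement genes by 0.94 in 18 of 20, macrophage genes by 0.83 in 19 of 22 and inflammation-linked transcription factors by 0.67 in 36 of 43 (camera, adjusted p = 2.34e-07, 5.97e-08, 2.3e-06 and 2.64e-11, with adjusted p = 0.296, 0.264, 0.32 and 0.197 with an estimated correlation). Of their members 6, 7, 6 and 11 passed adjusted over the list alone. Neutrophil genes lay the other way and did not pass (0.25, camera adjusted p = 0.222). The MHC class II master regulator Ciita was at 0.7997 ± 0.285 CPM against 5.44 ± 3.73 and complement C3 at 6.48 ± 3.39 against 44.4 ± 33.1. The lysosomal macrophage marker Cd68 was at 5.79 ± 3.36 against 20.4 ± 11.7, and the interferon-induced factor Irf1 at 10.8 ± 2.69 against 73.4 ± 55.0.

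Interferon-stimulated genes fell by 1.04 in 27 of 28 members and nerve injury genes by 0.42 in 21 of 24 (camera, adjusted p = 3.34e-05 and 0.029, with adjusted p = 0.621 and 0.725 with an estimated correlation). Heat shock (0.24, 14 of 15), glucocorticoid-responsive (0.27, 10 of 14), large-diameter neuron (0.13, 16 of 22), red blood cell (1.03, 9 of 13) and myelinating Schwann cell genes (0.14, 15 of 18) rose (camera, adjusted p = 1.29e-05, 0.00212, 0.00446, 0.00742 and 0.0175, with adjusted p = 0.264, 0.404, 0.474, 0.582 and 0.7 with an estimated correlation). Adjusted over the list alone, 0 members of these 7 lists passed. Examples were the glucocorticoid target Zbtb16 at 15.7 ± 2.51 CPM against 7.73 ± 0.712, the calcium buffer Pvalb at 359 ± 126 against 246 ± 91.8 and the injury-induced macrophage growth factor Csf1 at 16.5 ± 2.12 against 32.2 ± 14.9. Fixed inflammatory genes were lower, Tnf at 0.0837 ± 0.0807 CPM against 1.04 ± 0.595, Ccl2 at 15.6 ± 6.57 against 49.5 ± 24.5 and Cxcl10 at 13.5 ± 8.32 against 93.8 ± 82.9. Other genes with the smallest unadjusted p were Gstt2, Selenov, Cacybp, Gucy1a2 and Hist1h4b upward and Apobec1, Ccl12, Folr2 and Il18bp downward. EdgeR called 0 genes (smallest adjusted p 0.458) with 1043 at an unadjusted p under 0.05 (281 higher, 762 lower). That count was 1810 and 549 without Ctrl_solvent replicates 2 and 3 and 2557 without Sham_solvent replicate 2. DESeq2 called 35 (3 higher, 32 lower), and voom and the FPKM fits called 0. Groups did not overlap in 1217 genes (7.14%, chance 10%).

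The immune genes of Ctrl_solvent were high in replicates 1 and 3 and not in replicate 2. Cd8a was 7.41, 0.676 and 7.79 CPM in replicates 1, 2 and 3, and Cd3e, a subunit of the T cell receptor complex, 4.17, 0.325 and 3.81. Leaving out Ctrl_solvent replicates 1 and 3 was an alternative added after seeing the data. It leaves 1 library assumed to vary like the other groups, so only means against it are given here. The interferon (1.37), macrophage (0.22), complement (0.16), transcription factor (0.04), nerve injury (0.25) and red blood cell (-1.56) means turned. Leaving out Ctrl_solvent replicate 2 instead gave 252 genes, with lists such as inflammatory mediators at -2.15, macrophages at -1.35, complement at -1.48, transcription factors at -1.02, interferon at -2.23 and nerve injury at -0.74. T and B cell genes were at -1.12 without Ctrl_solvent replicate 1 or 3. Without Ctrl_solvent replicate 1 the interferon (-0.36) and red blood cell (0.50) calls ended and nerve injury was at -0.64. Without replicate 2 the glucocorticoid call ended (0.16) and red blood cell genes were at 2.34. Without replicate 3 the nerve injury mean turned (0.14), the red blood cell (0.28), large-diameter neuron (0.06) and Schwann cell (0.12) calls ended, and macrophage, interferon, complement, transcription factor and glucocorticoid means were -0.53, -0.51, -0.62, -0.44 and 0.41. Without Sham_solvent replicate 1 the nerve injury (-0.32) and Schwann cell (0.08) calls ended. Without Sham_solvent replicate 2 the glucocorticoid (0.13), large-diameter neuron (0.08), Schwann cell (0.08) and nerve injury (-0.22) calls ended, with red blood cell and interferon genes at 1.69 and -1.64. Without Sham_solvent replicate 3 the red blood cell call ended (0.22), and heat shock, nerve injury, Schwann cell and interferon means were 0.13, -0.70, 0.30 and -0.61.

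The comparison of Ctrl_solvent with Ctrl asks what solvent alone changed. Interferon-stimulated genes rose by 2.43 ± 0.18 in 28 of 28 members, 27 of them adjusted over the list alone (camera, adjusted p = 5.01e-14, but adjusted p = 0.332 with an estimated correlation). Gbp2 was at 269 ± 215 CPM against 20.9 ± 3.65 and Irf7 at 148 ± 125 against 7.81 ± 0.572. Inflammatory mediators (1.60 ± 0.22, 31 of 32), complement (1.68 ± 0.25, 19 of 20), macrophage (1.52 ± 0.20, 21 of 22) and T and B cell genes (1.85 ± 0.39, 12 of 14) rose, with 19, 15, 19 and 9 members adjusted over the list alone (camera, adjusted p = 1.19e-14, 1.38e-13, 3.67e-12 and 4.68e-08, all with adjusted p = 0.177 with an estimated correlation). The microglia and macrophage gene Aif1 was at 52.8 ± 33.9 CPM against 12.6 ± 4.06, the alarmin Il33 at 90.3 ± 11.4 against 47.6 ± 15.4, complement C7 at 51.2 ± 10.4 against 21.7 ± 1.94 and Cd8a at 5.29 ± 4.001 against 0.106 ± 0.0365. MHC class II genes (1.89 ± 0.14, 10 of 10), inflammation-linked transcription factors (0.80 ± 0.14, 38 of 43), cell cycle (0.62 ± 0.09, 24 of 24) and nerve injury genes (0.58 ± 0.19, 21 of 24) rose as well, with 10, 17, 1 and 1 members adjusted over the list alone (camera, adjusted p = 7.14e-09, 7.73e-10, 2.63e-06 and 0.0168, with adjusted p = 0.237, 0.224, 0.332 and 0.657 with an estimated correlation).

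Nociceptor genes fell in Ctrl_solvent by 0.29 in 21 of 27 members, large-diameter neuron genes by 0.19 in 18 of 22, cholesterol synthesis genes by 0.11 in 17 of 22, potassium channels by 0.10 in 18 of 28 and red blood cell genes by 1.35 in 11 of 13, with 0 members adjusted over the list alone (camera, adjusted p = 0.000472, 0.00203, 0.00637, 0.0384 and 0.0224, with adjusted p = 0.332, 0.436, 0.281, 0.657 and 0.628 with an estimated correlation). The sodium channel Scn10a was at 264 ± 37.8 CPM against 377 ± 83.0 and the pacemaker channel Hcn2 at 91.7 ± 18.9 against 128 ± 4.57. The calcium buffer Calb2 was at 61.5 ± 18.9 against 100 ± 12.8 and the natriuretic peptide gene Nppb, a mark of itch neurons, at 0.926 ± 0.231 against 36.1 ± 30.8. The high Nppb mean of Ctrl lay in replicates 2 and 3, which held almost no Y-linked reads. Ctrl replicate 1 lay near Ctrl_solvent, so the Nppb difference cannot be read as one of solvent. Thromboxane synthase Tbxas1 (chromosome 4, 4.22 ± 1.43 against 0.782 ± 0.342 CPM) and A2m (chromosome 4, 69.8 ± 16.4 against 26.3 ± 9.02 CPM) had the smallest unadjusted p (3.21e-06 and 5.87e-06, edgeR adjusted p = 0.05002 for both, just above the threshold). They were followed by C7, Ripk3 and Tent5a upward and Dpf1, Dcakd, the fatty acid carrier Slc27a4, Selenov and S100a3 downward. EdgeR called 0 genes with 2218 at an unadjusted p under 0.05 (1420 higher, 798 lower), or 1234 without Ctrl_solvent replicate 3. DESeq2 called 468 (406 higher, 62 lower), voom 2 (Tbxas1 and A2m) and the FPKM fits 0. Groups did not overlap in 2829 genes (16.6%, chance 10%).

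Without Ctrl_solvent replicates 1 and 3, which leaves 1 library of that group, the interferon mean against Ctrl was 0.03, that of macrophage genes 0.48 and that of T and B cell genes 0.52. The red blood cell mean turned to 1.26. Without Ctrl_solvent replicate 2 edgeR called 734 genes. Ctrl replicates 2 and 3 held almost no reads of Y-linked genes (Eif2s3y at 1 and 0 reads, against 2180 to 6568 in the other libraries), and leaving them out was also added afterwards. It leaves 1 Ctrl library, assumed to vary like the other groups. The calls that ended were those of nociceptor (-0.07, camera adjusted p = 0.350), potassium channel (-0.08), cholesterol synthesis (-0.09) and red blood cell genes (-0.70). Leaving out Ctrl_solvent replicate 3 also ended the nerve injury (0.04), large-diameter (-0.10), potassium channel (-0.04) and red blood cell (-0.58) calls. Leaving out Ctrl replicate 3 ended the nociceptor call (-0.16) and the potassium channel call, whose mean turned (0.00219), Ctrl replicate 1 the nerve injury call (0.49), Ctrl replicate 2 the red blood cell call (-0.70), and Ctrl_solvent replicate 1 the potassium channel (-0.08) and red blood cell (-0.81) calls. Without Ctrl_solvent replicate 2 the nerve injury, potassium channel, red blood cell and cell cycle means were 0.90, -0.18, -2.65 and 0.93, and potassium channels were at -0.19 without Ctrl replicate 2 and cell cycle genes at 0.41 without Ctrl replicate 1.

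The comparison of NPP_solvent with Ctrl_solvent sets the NPP label against the Ctrl label, both with solvent. Replicates 1 and 3 of Ctrl_solvent held its high immune levels. Inflammatory mediators fell by 1.22 in 32 of 32 members, cell cycle genes by 0.85 in 24 of 24, T and B cell genes by 1.78 in 13 of 14 and MHC class II genes by 1.66 in 10 of 10 (camera, adjusted p = 1.43e-16, 1.43e-16, 7.21e-13 and 1e-11, with adjusted p = 0.177, 0.176, 0.0916 and 0.179 with an estimated correlation). Among them 18, 11, 10 and 7 members passed adjusted over the list alone. Macrophage genes fell by 0.81 in 21 of 22, inflammation-linked transcription factors by 0.54 in 35 of 43 and complement genes by 0.74 in 17 of 20, with 4, 7 and 1 members adjusted over the list alone (camera, adjusted p = 4.05e-08, 6.79e-07 and 6.58e-06, with adjusted p = 0.295, 0.325 and 0.325 with an estimated correlation). Nociceptor genes rose by 0.27 ± 0.06 in 24 of 27 members (camera, adjusted p = 6.58e-06, and adjusted p = 0.295 with an estimated correlation). The neurotrophic factor receptor Gfra3 was at 53.2 ± 5.57 CPM against 38.6 ± 6.63 and the cold channel Trpm8 at 75.5 ± 11.4 against 58.6 ± 9.43. Interferon-stimulated genes (28 of 28), immediate early genes (17 of 24) and neutrophil genes (11 of 12) fell by 0.61, 0.35 and 0.59 and Schwann cell genes rose by 0.14 in 16 of 18 (camera, adjusted p = 0.0143, 0.0107, 0.038 and 0.0206, with adjusted p = 0.645, 0.607, 0.607 and 0.607 with an estimated correlation). Adjusted over the list alone, 0 members of these 4 lists and 0 nociceptor genes passed.

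The endotoxin receptor Cd14 (chromosome 18) was at 2.13 ± 0.229 CPM in NPP_solvent against 9.54 ± 5.67 in Ctrl_solvent and A2m at 33.2 ± 5.94 against 69.8 ± 16.4. The RNA-binding splicing factor Celf4 (chromosome 18) was at 62.4 ± 5.41 against 46.9 ± 6.56 and Tmem158 at 10.2 ± 3.72 against 4.17 ± 0.421. Celf6, Scn4a and Npy1r completed the upward genes and Rab3il1, Ncf1 and Tnfaip2 the downward ones. Atf3 (45.5 ± 34.9 against 40.3 ± 47.1 CPM) did not differ beyond its spread, and the nerve injury list did not pass. EdgeR called 0 genes (smallest adjusted p 0.509) with 937 at an unadjusted p under 0.05 (254 higher, 683 lower), or 477 and 1622 without Ctrl_solvent replicates 1 and 2. DESeq2 called 46 (1 higher, 45 lower), and voom and the FPKM fits 0. Groups did not overlap in 1289 genes (7.56%, chance 10%). Without Ctrl_solvent replicates 1 and 3, which leaves 1 library of that group, the interferon mean turned to 1.79, while edgeR called 188 genes without Ctrl_solvent replicate 2. The interferon mean also turned without Ctrl_solvent replicate 1 (0.07) or NPP_solvent replicate 3 (0.21). Leaving out Ctrl_solvent replicate 3 ended the interferon (-0.10), immediate early (-0.16) and Schwann cell (0.11) calls, and Ctrl_solvent replicate 1 or 2 the neutrophil call (-0.29 and -0.57). Leaving out NPP_solvent replicate 3 also ended the immediate early (-0.22) and Schwann cell (0.08) calls, NPP_solvent replicate 2 those of immediate early and neutrophil genes (-0.32 and -0.62), and NPP_solvent replicate 1 that of neutrophil genes (-0.48). The nociceptor mean was 0.17 without Ctrl_solvent replicate 1 or NPP_solvent replicate 3. Without Ctrl_solvent replicate 2 the macrophage, inflammatory, interferon, complement, immediate early and transcription factor means were -1.32, -1.997, -1.81, -1.28, -0.57 and -0.88. Without replicate 3 those of macrophage, neutrophil, complement and transcription factor genes were -0.52, -0.89, -0.44 and -0.32. Complement genes were at -0.48 without NPP_solvent replicate 3, and interferon genes at -0.99 and -1.06 without NPP_solvent replicates 1 and 2. With the gene length covariate the interferon (-0.50), immediate early (-0.23) and neutrophil (-0.54) calls ended, and nerve injury (0.49), satellite glia (0.12) and skeletal muscle (0.34) lists passed.

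The difference of the herb effect between the NPP and Sham arms asks whether the herb acted differently with and without the model. Nociceptor genes differed by -0.31 (herb effect -0.06 in NPP and 0.25 in Sham), interferon-stimulated genes by -1.27 (-1.37 and -0.10), neutrophil genes by 1.48 (0.76 and -0.72), and red blood cell genes by 2.56 (1.53 and -1.02). Fibroblast genes differed by 0.51 (0.13 and -0.39), immediate early genes by 0.54 (0.18 and -0.36) and glucocorticoid-responsive genes by 0.25 (-0.17 and -0.42). Camera gave adjusted p of 0.000116, 0.000122, 4.25e-05, 3.14e-05, 0.000199, 0.000116 and 0.0417 in that order, with adjusted p = 0.845, 0.898, 0.845, 0.845, 0.898, 0.869 and 0.898 with an estimated correlation. Adjusted over the list alone, 1 fibroblast gene passed, Fbln1 (1.18 ± 0.28), and 0 members of the others. The red blood cell and neutrophil lists each passed camera in 6 of the 8 comparisons, with means of both signs (-1.35 to 2.56 and -0.84 to 1.48). Blood left in the ganglia was not tested as their source. The smallest edgeR adjusted p (0.83) belonged to LOC120102105, a placeholder symbol set aside here. Among named genes Gjb2 was next (difference 1.94 ± 0.39, edgeR adjusted p = 0.862), followed upward by Rn45s (2.16 ± 0.49), Fbln1, the insulin-like growth factor Igf2 (2.18 ± 0.52) and Cemip (1.13 ± 0.29), and downward by Kcnn1 (-0.88 ± 0.25), Gpr35, Slc6a7, Mmp25 and Spata13. EdgeR called 0 genes with 580 at an unadjusted p under 0.05 (322 higher, 258 lower). That count was 342 and 2341 without Sham_solvent replicates 1 and 2, 1181 without NPP_herb replicate 3, 913 without NPP_solvent replicate 2 and 362 with the gene length covariate. DESeq2 called 2 (LOC120102105 and Gjb2), and voom and the FPKM fits 0. Leaving out NPP_solvent replicate 2 ended the interferon and fibroblast calls (-0.83 and 0.38). The interferon mean was -2.10 without NPP_solvent replicate 3 and -0.84 without Sham_solvent replicate 3. The gene length slope as a covariate ended the immediate early call (0.29) and moved the nociceptor mean to -0.11, while large-diameter neuron (0.12), cholesterol synthesis (-0.10), heat shock (0.18) and cell cycle (0.26) lists passed with it. The glucocorticoid call was lost without any of NPP_herb replicate 1 (0.16) or 3 (0.23), NPP_solvent replicate 2 (0.26) or 3 (0.05), Sham_herb replicate 1 (0.08) and Sham_solvent replicate 2 (0.105), or with DESeq2 size factors (0.27). Its mean was 0.43 without NPP_solvent replicate 1 and 0.38 without either Sham_herb replicate 2 or Sham_solvent replicate 3.

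The effects of the model in the solvent and herb arms were also compared across the 17043 genes. The log2 fold changes of NPP_solvent against Sham_solvent and of NPP_herb against Sham_herb, which share no library, correlated at r = -0.0994 with a jackknife SE over libraries of 0.139 (Spearman's rho -0.111), so r lay within 1 SE of 0. In 100 simulations without any effect r ran from -0.0516 to 0.0353, with a covariance of 0.000212 against -0.0117 observed. This range is narrow beside the jackknife SE of 0.139, so r lying outside it is no evidence of opposed effects. The nerve injury list passed camera in both arms (0.70 and 0.77), though not with an estimated correlation (camera adjusted p = 0.988 and 0.683), and single libraries ended each call (0.46 without NPP_solvent replicate 1, 0.50 without Sham_solvent replicate 2 and 0.33 without NPP_herb replicate 2). With each library left out in turn, r ran from -0.156 to -0.00868. The fold changes of NPP_solvent against Sham_solvent and of NPP_herb against NPP_solvent correlated at r = -0.431 (rho -0.293), but these share the NPP_solvent libraries with opposite sign. Simulated unchanged groups gave a mean of -0.491 (-0.516 to -0.462), with a covariance of -0.0539 observed and -0.0648 simulated. Genes are not independent replicates, so no p-value is given.

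The lists named next passed in none of the 8 comparisons, though with the gene length covariate satellite glia, circadian clock and pan-neuronal genes passed in 1 each, the last in Ctrl_solvent against Ctrl (-0.10). Satellite glia genes, which mark the glia around neuron bodies, lay between 0.02 and 0.08 (smallest camera adjusted p 0.119), pan-neuronal genes between -0.10 and 0.07 (0.0537), spinal cord genes between -0.19 and 0.48 (0.0888) and adipocyte genes between -0.35 and 0.35 (0.222). Circadian clock genes lay between -0.15 and 0.18 (0.269), hypoxia genes between -0.07 and 0.06 (0.141) and NRF2 and AhR targets, which answer oxidants and plant compounds, between -0.15 and 0.17 (0.269). The Y-linked genes Kdm5d and Eif2s3y were at 16.2 ± 4.06 and 120 ± 4.19 CPM in NPP_solvent and 12.7 ± 4.54 and 134 ± 4.62 in Sham_solvent, and Ddx3y, which the table places on chromosome 13, at 2.68 ± 1.12 and 2.43 ± 0.844.

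**Figure D3:**
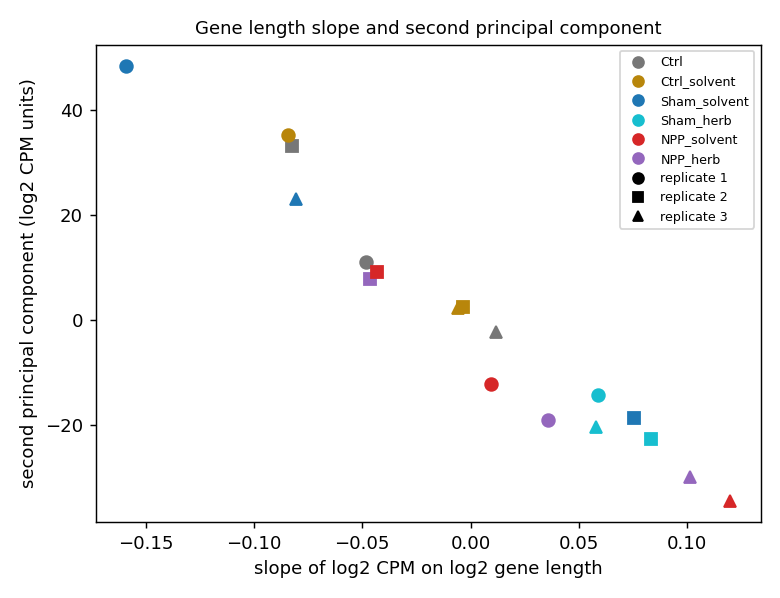
Slope of log2 CPM on log2 gene length (x axis, log2 units per doubling of length) against the second principal component of log2 CPM (y axis) for the 18 libraries, with colors for groups. The slope ran from -0.159 in Sham_solvent replicate 1 to 0.120 in NPP_solvent replicate 3, and the libraries lie along a line (r = -0.977).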

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

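The herb effect on 7 gene lists differed between the NPP and Sham arms in a test of the difference itself, which is what marked these results. The differences were -0.31 for nociceptor genes, 1.48 for neutrophil genes, 2.56 for red blood cell genes, 0.51 for fibroblast genes, -1.27 for interferon-stimulated genes, 0.54 for immediate early genes and 0.25 for glucocorticoid-responsive genes. None passed camera with an estimated correlation, where the smallest adjusted p of these was 0.845. Of 30 splits of the 12 libraries, 18 gave as many lists as the real 7, and the highest other gave 13, so chance is not excluded. For genes, where edgeR called 0 in the real split (580 at an unadjusted p under 0.05, 2 by DESeq2, 0 by voom), all 30 gave as many, which was fixed in advance, 19 gave as many at an unadjusted p under 0.05 (highest other 4224), and 1 split called 488, which points to a structure of the samples other than their groups.

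The tests of the injury genes below were all chosen after the result was seen. Injury genes such as Atf3 and Npy were high in libraries of several labels, with Npy at 196 CPM in Ctrl_solvent replicate 3, 112 in Sham_herb replicate 3 and 3.18 and 1.23 in replicate 3 of NPP_solvent and NPP_herb. A difference in scaling is argued against, since the pan-neuronal score ranged over 0.258 on the log2 scale and the injury score over 2.15. Labels exchanged between NPP and other libraries could explain it and stay open, since 3 libraries outside the NPP groups lay above the widest gap in Atf3 (15.9 to 29.4 CPM) and 2 NPP libraries below it, and nothing in the tables gives the origin of a library. All of the libraries so counted are numbered 3. The biological explanation, the NPP label, had its needed value in the mean. The injury score was 0.46 ± 0.71 (SD) in the NPP libraries and -0.23 ± 0.55 in the others (exact two-sided permutation p = 0.0373). This test takes the labels as right and was chosen after the high NPP libraries were seen. The NPP label does not account for the 3 high libraries outside NPP or the 2 low NPP libraries.

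The tests of the immune genes in Ctrl_solvent were all chosen after the result was seen, as were Cxcl9 and Gzmb, single genes chosen after their values were seen. T cell and MHC class II genes were high in Ctrl_solvent replicates 1 and 3 and not in replicate 2, with the interferon-gamma-induced chemokine Cxcl9 at 51.7, 80.2 and 2.33 CPM and the killer cell protease Gzmb at 6.44, 10.6 and 0.027 in replicates 1, 3 and 2. Blood left in the ganglia is argued against, since the higher red blood cell score of these 2 libraries was -1.79. Nerve injury is argued against in replicate 1, with an injury score of -0.32, and may still play a part in replicate 3, with 1.19, where it cannot be told apart from other causes in 1 library. An infection or immune reaction in single animals was not tested, and the design names no such group.

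The test of the length slope against the second component, and those with the length slope as a covariate, were chosen after the data were seen. Log2 levels tilted with gene length from library to library, and the slope followed the second principal component over the 18 libraries (r = -0.977, permutation p = 1e-05, the smallest that the resamples can give, adjusted 2e-05 over 2 correlations, and r = -0.964 without Sham_solvent replicate 1 and NPP_solvent replicate 3). With the slope as covariate the means of potassium channel (-0.0205) and nociceptor genes (0.0422) in Sham_herb against Sham_solvent were near 0, so a length bias may lie behind these calls. It is argued against as the whole cause of the nerve injury rise in NPP_solvent against Sham_solvent (0.99), and stays open for the nociceptor rise there (0.21, from 0.36). A higher share of neurons as the source of the slope stays open, since r with the pan-neuronal score was 0.183 (permutation p = 0.47) and 0.0507 without the same 2 libraries.

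Each pairwise comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. EdgeR called 0 genes in each real split, so that all 10 gave as many was fixed in advance, and the highest other was 1582 for NPP_solvent against Sham_solvent, 0 for NPP_herb against NPP_solvent, 0 for Sham_herb against Sham_solvent, 0 for NPP_herb against Sham_herb, 285 for Sham_solvent against Ctrl_solvent, 73 for Ctrl_solvent against Ctrl and 2 for NPP_solvent against Ctrl_solvent, beside the counts at an unadjusted p under 0.05 and by DESeq2 and voom given with each comparison. The 1582 came from the split that put NPP_solvent replicates 1 and 3 with Sham_solvent replicate 2, the 285 from Sham_solvent replicates 1 and 3 with Ctrl_solvent replicate 2, and the 73 from Ctrl_solvent replicates 1 and 3 with Ctrl replicate 2, which points to a structure of the samples other than their groups. At an unadjusted p under 0.05, in the same order, the real splits held 967, 319, 1686, 238, 1043, 2218 and 937 genes, the splits with as many were 4, 8, 3, 9, 6, 1 and 5, and the highest others held 4761, 2173, 2868, 600, 3105, 2101 and 1886, so that the real split was the highest of 10 for Ctrl_solvent against Ctrl, whose 2218 was 1234 without Ctrl_solvent replicate 3 and 3231 without replicate 2. For lists, in the same order, the real counts were 4, 6, 10, 9, 14, 14 and 12, the splits with as many 8, 5, 3, 6, 2, 3 and 5, and the highest others 11, 14, 15, 14, 16, 19 and 16. In the split with 1582 genes the length slopes were 0.00950, 0.120 and 0.0754 on the side named above and -0.0430, -0.159 and -0.0806 on the other. In the split with 285 genes the first principal component was -17.7, -10.1 and -20.8 against 19.6, 57.2 and 64.9. Both were looked at after the splits were seen, and a cause was not tested.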

How the results depend on the processing

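With other settings, the number of genes called stayed at 0 in most cases and the number of lists moved. Exceptions for genes were voom in Sham_herb against Sham_solvent (1131) and Ctrl_solvent against Ctrl (2), no low-count filter (1) and the length covariate (1) in Ctrl_solvent against Ctrl, no replicate 3 in NPP_herb against Sham_herb (1), and DESeq2 in NPP_herb against Sham_herb (2), Sham_solvent against Ctrl_solvent (35), Ctrl_solvent against Ctrl (468), NPP_solvent against Ctrl_solvent (46) and the difference of herb effects (2). The gene called without any replicate 3 was the injury gene Npy, with a log2 fold change of 6.11. The alternatives that use the length covariate or leave out several libraries were chosen after seeing the data. Leaving out 1 library gave 0 to 252 genes in Sham_solvent against Ctrl_solvent, 0 to 734 in Ctrl_solvent against Ctrl, 0 to 188 in NPP_solvent against Ctrl_solvent (each highest without Ctrl_solvent replicate 2), 0 to 2 in NPP_herb against Sham_herb (highest without NPP_herb replicate 2), 0 to 1 in the difference of herb effects (without NPP_solvent replicate 1) and 0 to 0 in the other 3. List counts were 0 in all 8 with an estimated correlation, and with fry 0, 0, 0, 0, 2, 6, 1 and 0 in the order of the report. They were 9, 11 and 9 without any replicate 3 in NPP_solvent against Sham_solvent, NPP_herb against NPP_solvent and Sham_solvent against Ctrl_solvent, 8 with the length covariate in NPP_solvent against Sham_solvent, and 7, 7 and 6 without Ctrl_solvent replicates 1 and 3 in the 3 comparisons with that group. Leaving out 1 library gave, in the order of the report, 2 to 10, 5 to 10, 5 to 12, 5 to 15, 10 to 15, 11 to 17, 10 to 16 and 5 to 11 lists.

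List means that turned were, with the length covariate, potassium channels in Sham_herb against Sham_solvent (-0.0205). Without any replicate 3 they were skeletal muscle in NPP_herb against Sham_herb (-0.0153), red blood cell in Sham_solvent against Ctrl_solvent (-0.55), potassium channels in Ctrl_solvent against Ctrl (0.0627) and interferon in NPP_solvent against Ctrl_solvent (0.73). Without Ctrl_solvent replicates 1 and 3 they were, in Sham_solvent against Ctrl_solvent, nerve injury (0.25), macrophage (0.22), red blood cell (-1.56), interferon (1.37), complement (0.16) and transcription factors (0.0439), in Ctrl_solvent against Ctrl, nerve injury (-0.0717), potassium channels (0.0551), red blood cell (1.26) and cell cycle (-0.0197), and in NPP_solvent against Ctrl_solvent, macrophage (0.23), inflammatory (0.0704), interferon (1.79), complement (0.35), immediate early (0.13) and transcription factors (0.17). Leaving out 1 library gave -0.0028 to 0.19 for endothelial genes in NPP_herb against Sham_herb, -0.74 to 0.14 for nerve injury in Sham_solvent against Ctrl_solvent, -0.19 to 0.00219 for potassium channels in Ctrl_solvent against Ctrl and -1.81 to 0.21 for interferon in NPP_solvent against Ctrl_solvent, and the cause was not tested. Of the other values, 706 list values stayed on their side of the threshold and 276 were weaker, and 13 of the effect correlation stayed within the spread. With replicate numbers as a block, genes stayed at 0 everywhere and lists were 4, 5, 10, 8, 14, 14, 11 and 7. No pairing by number was seen. Same-number libraries correlated at a mean of -0.00626 (-0.282 to 0.231) after group means were removed, and 4 of 18 were closest to their own number. A mean near 0 cannot exclude an effect that libraries of one number share with opposite signs between groups. The correlation over genes called could not be computed, since no gene was called.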

Other observations

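Voom with quality weights called 1131 genes in Sham_herb against Sham_solvent and edgeR 0 (1686 at an unadjusted p under 0.05, or 447 with the gene length covariate, 0 by DESeq2). Length slopes were 0.0589, 0.0835 and 0.0580 in Sham_herb replicates 1, 2 and 3 and -0.159, 0.0754 and -0.0806 in those of Sham_solvent. Voom was not run with that covariate, so a length bias behind its calls stays open. The single genes named here were chosen after their values were seen, and no enrichment among the called genes was tested. Manf and Creld2, secreted proteins induced when unfolded proteins build up, had voom log2 fold changes of -0.65 and -0.84, and the adhesion molecule Ncam1 and the lipid transfer protein Vps13d 0.48 and 0.61 (edgeR adjusted p = 0.491 for each). The chaperone Hspa5 of the same compartment was at 442, 449 and 684 CPM in Sham_solvent replicates 1, 2 and 3 and at 430, 429 and 417 in Sham_herb, so its higher Sham_solvent mean lay in 1 library.

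Nppb, a peptide gene of itch neurons, and Reg3b, a lectin gene of injured neurons, were high in the same few libraries, and both were chosen after their values were seen. Nppb was at 47.1 and 59.8 CPM in Ctrl replicates 2 and 3 and 22.2 in NPP_solvent replicate 3, against 0.683 to 2.17 in the other libraries. Reg3b was at 67.1 and 97.1 CPM in the same Ctrl libraries and 36.6 in NPP_solvent replicate 3, and Ctrl replicate 1 was at 1.22 and 0.516 CPM for Nppb and Reg3b.

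The test of Kdm5c, Kdm6a and Ddx3x below was chosen after the result was seen. Ctrl replicates 2 and 3 held 1 and 0 reads of the Y-linked Eif2s3y, against 2180 to 6568 in the other 16 libraries. The Y-linked Kdm5d and Uty had 0 reads in both libraries, against 214 to 902 and 95 to 424 in the others. A candidate explanation is that these 2 came from female animals, and the X-linked partner Eif2s3, which escapes inactivation, was higher in them by 0.43 on the log2 scale, as that explanation needs. The genes Kdm5c, Kdm6a and Ddx3x were higher by 0.27 together, which leaves it open, since Kdm5c lay above the other libraries (41.0 to 42.4 CPM against 22.4 to 36.02), as female animals would show, but Kdm6a (8.73 to 9.67 against 4.93 to 10.5) and Ddx3x (284 to 302 against 230.3 to 312) overlapped them. The sex of the animals is not given in the sources used here, Xist is not listed in the table used, and Ctrl against Ctrl_solvent would mix sex with solvent if the explanation holds.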
